A study of Mus musculus with 12 samples.

How the data were processed

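Cerebellar messenger RNA of 12 mice was compared between 2 genotypes, 6 WT and 6 cKO, each library coming from the cerebellum of a separate animal as the series describes it. The groups came from the genotype given for each sample, and replicate numbers only name libraries in the order of deposit within a group. Per the labels' protocols, RNA was extracted from fresh tissue, libraries were made with a stranded mRNA kit, and all samples were multiplexed over the same lanes of an Illumina sequencer, so no lane batch separates the genotypes. The labels give no litter, age, sex or dissection date.

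The authors deposited raw read counts per gene symbol, not normalised, in a table of 18394 genes. STAR, DESeq2 and the mm10 build are named without versions, per the submitters' processing notes. The tool that counted reads, its strand setting and its annotation are not given in the sources used here, nor is the rule by which genes were listed. The authors also deposited a DESeq2 comparison with a log2 fold change and its standard error, and with a p-value and adjusted p-value per gene, per the file headers. Its standard errors reach at most 0.0488 even for rare genes and its folds are smaller than those computed here, so its fold changes appear to be shrunken towards 0. The sign convention is not stated there, and was read from the 400 genes called in both analyses, which all had the same sign with positive meaning higher in cKO. An adjusted p was absent for 3214 genes of that table. All 12 count columns were matched to samples by their own identifiers, and 0 columns of sample values were left unmatched. Rows without a gene name numbered 0.

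Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, leaving 15467, library sizes were scaled by TMM, and genotype was tested with the quasi-likelihood test of edgeR (glmQLFit, glmQLFTest) and Benjamini-Hochberg adjustment at 0.05, with no fold minimum and no covariate. Levels are given as CPM, counts scaled to a common library size after TMM. Standard errors and 95% intervals were derived from the test statistic. The target and driver genes, Crhr1 and Gabra6, were also tested by an exact permutation over the 924 assignments of 12 libraries to 2 groups of 6. With 6 libraries per group the smallest two-sided p of that test is 0.00216.

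The rule for named genes was fixed before the data were examined: Crhr1 and Gabra6, the 12 genes with the smallest p in each direction and a mean of at least 1 CPM, and the 4 members of each gene list with the smallest p. Some genes that the rule names are not reported here, though counts include them. Calls and counts of list members outside this rule are named only to complete a count. The 35 gene lists held 549 genes, 500 of them tested, and covered cell types, synaptic and signalling genes, stress and housekeeping responses and the neighbourhoods of Gabra6 and Crhr1. They were tested as sets with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 33 lists with at least 3 tested members. Erythrocyte markers, with 2 tested, were too few for a set test. Mitochondrially encoded genes were not analysed here. Of the 5 lists that passed, 0 passed with a correlation estimated for each list, although 4 of the 33 had an unadjusted p under 0.05 that way, and fry, which asks whether the genes of a set move on balance in one direction, passed 5 lists, 3 of them among those 5 (not microglia or the unfolded protein response) and 2 others (granule cell development and growth factors). Lists share members: Gabra6, for example, is in the granule cell and the GABA receptor lists, and some genes near Gabra6 are in both the GABA receptor and the chromosome 11 lists.

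Gene positions came from GENCODE release M21 (mm10), matched by symbol for 14878 of the 15467 tested genes (96.2%). Called genes within 10 Mb of Gabra6 or Crhr1 were compared with the rest by two-sided Fisher's exact tests, leaving those 2 genes out. Several named genes overlap annotated genes, such as Chrnb4, Nos1, Rasa4, Ltbp2, Cntnap4, Itpr3, Eomes, Grk5 and Rab37 on the opposite strand and Syt1, Cadm1 and Atp2b4 on the same strand, and Cx3cr1 overlaps several genes. Their counts could hold reads of the overlapping gene, since the counting rule is not known.

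Pairs of libraries in a group differed by more than counting noise, with a chi-square per degree of freedom of at least 2.47 over genes with a summed count of 100 or more, so each library was counted as a separate sample. All 12 libraries carried counts of Y-linked genes and at most 12 counts of Xist, so a planned sex covariate could not be fitted.

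The gene test and the list test were tested on simulated counts for the cKO against WT comparison, drawn for 15467 genes from the real means and library sizes in 5 simulations. The changed genes had a mean of at least 1 CPM. Of 250 changed genes per fold, 31.2% were recovered at a fold of 1.1, 76.4% at 1.2, 95.2% at 1.5 and 99.6% at 2. False calls made up 4.11% of calls. A list shifted by 0.1 on the log2 scale was found in 5 of 5 simulations, and 2 of 160 tests of lists without a shift passed. Simulated genes varied independently of each other, whereas the real lists had estimated correlations of −0.104 (CRF system) to 0.810 (choroid plexus). The simulations therefore do not show how often lists of correlated genes pass by chance. The window test was run on calls drawn at random from the same genes. With further calls planted near Gabra6 it passed in 5 of 5 simulations, and with the random calls alone in 1 of 5 (Fisher's exact p = 0.0447). More calls were planted than the 5 found within 5 Mb in the data, so an excess of the observed size was not tried.

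Alternatives fixed in advance were size factors of DESeq2, upper-quartile scaling, no filter, a filter of 1 CPM in 6 libraries, DESeq2 1.42.0, limma-voom with quality weights, surrogate variables from sva 3.50.0, a test against a fold minimum of 1.2, leaving out each library in turn, camera with an estimated correlation, fry, and windows of 5 and 20 Mb. Added after the data were seen were a score of 21 forebrain and midbrain genes as a covariate, counts thinned to the smallest library (23.8 M), the fit without the 4 libraries with the highest score, and 2 list tests without chosen members. The score is the mean of scaled log2 CPM over those genes. A change of sign was counted as a reversal only where the value passed its threshold in the main or the alternative fit.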

Results

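Messenger RNA was profiled by stranded mRNA sequencing of the cerebella of 12 mice, 6 wild type (WT) and 6 labelled as Crfr1 knockouts made with the Δα6-Cre driver (cKO). Crfr1 is the type 1 receptor for corticotropin-releasing factor and appears in the table under the symbol Crhr1. The driver is named after the α6 subunit of the GABA-A receptor, encoded by Gabra6, a gene typical of cerebellar granule cells. Each library comes from a whole cerebellum, so every value averages granule cells, Purkinje cells, interneurons and glia. Library totals ran from 23.8 to 62.1 M counts (M, counts in units of 1e6). WT libraries averaged 36.3 ± 13.9 M (SD, n = 6) and cKO libraries 49.1 ± 10.01 M (SD, n = 6), a difference within the spread of the libraries (two-sided exact permutation test, p = 0.0974). The design poses a single question: how cerebellar gene expression differs between these cKO and WT mice. The labels name no group that carries the driver without the knockout. Effects of receptor loss, of the driver and of DNA linked to either can therefore not be told apart for any gene.

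Crhr1 itself showed no difference beyond the spread between libraries, whereas Gabra6 fell by 23.3% in cKO cerebella. Crhr1 (chromosome 11, 104132855 to 104175523, mm10) measured 97.6 ± 4.31 CPM (counts scaled to a library of 1 M) in WT and 98.8 ± 6.00 in cKO (SD, n = 6 each). Its log2 fold change was 0.02 (SE 0.04, 95% interval −0.06 to 0.10; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.889). An exact permutation test of its log2 level gave p = 0.727, and each library held 2395 to 6282 Crhr1 counts, so depth was not limiting. Counts summed over a whole gene include its undeleted parts, and cells outside the driver's reach add their own transcripts, so this total does not check the knockout. Gabra6 (chromosome 11, 42306437 to 42321072) went from 813 ± 56.1 to 623 ± 30.0 CPM (SD, n = 6 each; log2 fold change −0.38, SE 0.04, edgeR adjusted p = 1.45e-05). All 6 cKO libraries lay below all 6 WT libraries, which gives the smallest exact permutation p possible here, 0.00216.

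**Figure D1:**
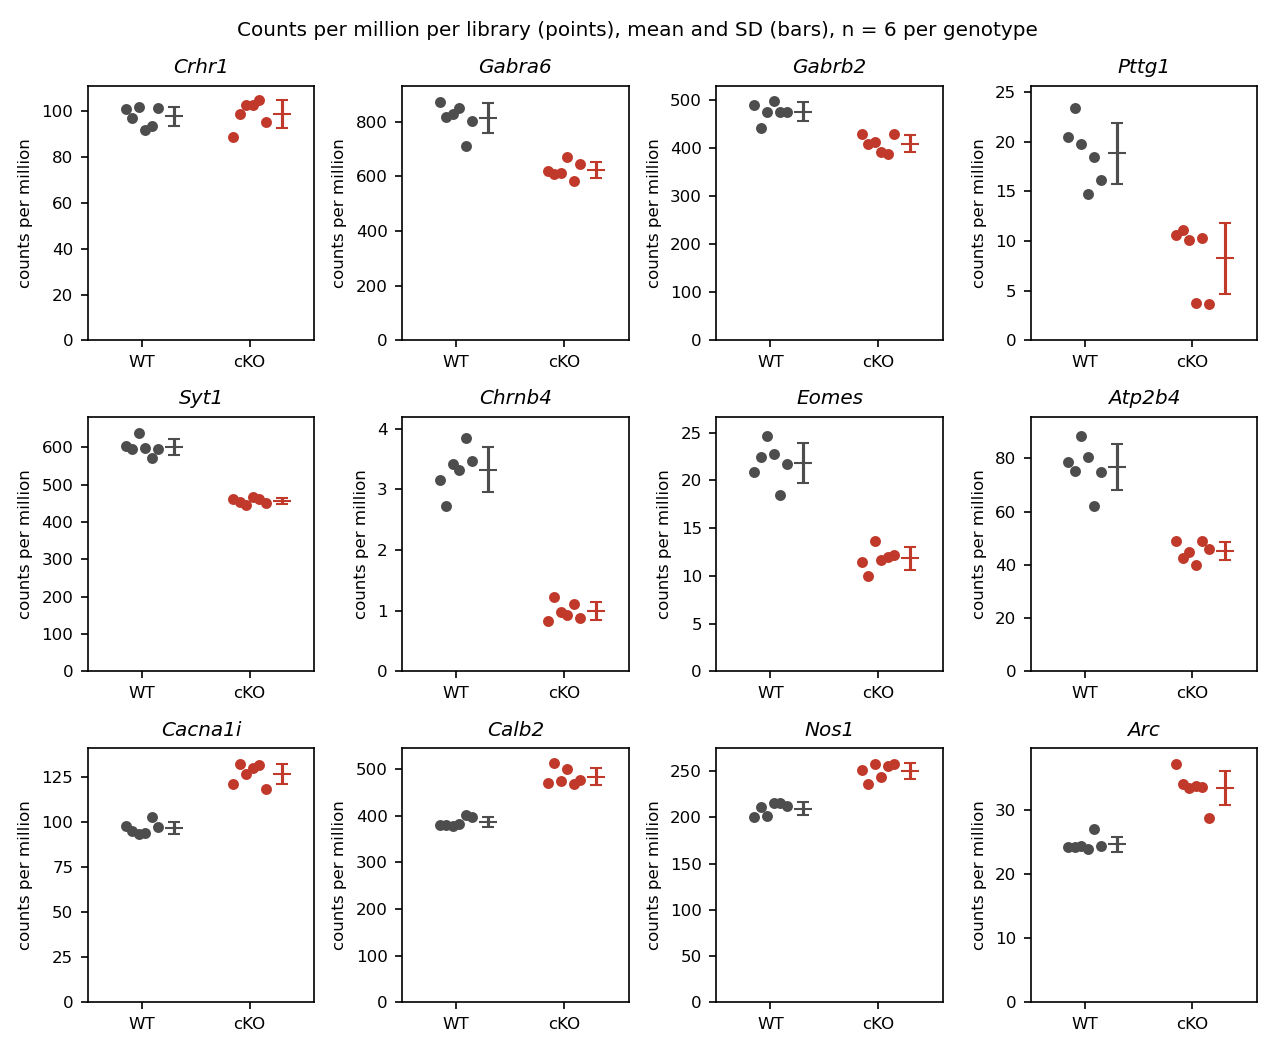
CPM of 12 genes in each library, with the mean and SD of the 6 WT and 6 cKO libraries beside the points; each vertical axis starts at 0. Crhr1 overlapped between the genotypes, while for the other 11 genes shown no cKO library reached the WT range.

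Across the cerebellum, 409 of 15467 tested genes differed between the genotypes, 196 higher and 213 lower in cKO. Neuronal genes were among those with the strongest evidence. Syt1, the calcium sensor of synaptic vesicle release, fell by 23.9%. Eomes, a transcription factor that marks unipolar brush cells, fell by 45.7%. Among the genes that rose were Cacna1i, a T-type calcium channel subunit, and Calb2, which encodes the calcium-binding protein calretinin. Most changes were small, with a median fold of 1.14 among the called genes, 30 above 1.5-fold and 8 above 2-fold. Over all 15467 tested genes, whether called or not, the 6 values of one genotype lay entirely above the 6 of the other in 324, or 2.095%, where chance gives 0.216%.

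The 12 genes with the smallest p among those lower in cKO included Syt1, Chrnb4, Syne2, Cadm1, Eomes, Atp2b4, Megf11, Grk5, Rab37, Shisa8 and Kcnc4. Syt1 went from 601 ± 21.6 to 457 ± 7.81 CPM (SD, n = 6 each; log2 fold change −0.39, SE 0.02, edgeR adjusted p = 2.46e-08). Chrnb4, the β4 subunit of nicotinic acetylcholine receptors, had the largest fold of these 12: it fell by 70.2%, from 3.32 ± 0.37 to 0.99 ± 0.15 (SD, n = 6 each). Its neighbour Chrna3, the α3 nicotinic subunit, which was singled out after its values were seen, fell by 57.5% (edgeR adjusted p = 0.00145). Eomes went from 21.8 ± 2.06 to 11.8 ± 1.17 and Atp2b4, a plasma membrane calcium pump, from 76.6 ± 8.62 to 45.2 ± 3.54 (SD, n = 6 each). The nuclear envelope gene Syne2 fell by 31.8%, the adhesion gene Cadm1 fell by 24.6% and the kinase gene Grk5 fell by 31.7%. Kcnc4, a voltage-gated potassium channel subunit, fell by 21.3%, Shisa8 fell by 30.2%, Rab37 fell by 26.5% and Megf11 fell by 16.5%.

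The corresponding 12 genes higher in cKO were Cacna1i, Ltbp2, Calb2, Cntnap4, Itpr3, Sh3bgr, Gcnt1, Rasa4, 6530403H02Rik, Sez6, Nos1 and Arc. Cacna1i rose from 96.5 ± 3.46 to 127 ± 5.64 CPM (SD, n = 6 each; log2 fold change 0.39, SE 0.03, edgeR adjusted p = 3.90e-07). Ltbp2, an extracellular matrix protein, rose 1.40-fold, and Calb2 rose 1.25-fold, from 386 ± 9.92 to 483 ± 18.2 (SD, n = 6 each). Itpr3, an inositol trisphosphate receptor that releases calcium from internal stores, rose 1.36-fold. Nos1, the neuronal nitric oxide synthase, rose 1.19-fold, and Arc, an activity-regulated gene of excitatory synapses, 1.35-fold, from 24.7 ± 1.16 to 33.5 ± 2.66 (SD, n = 6 each). The neurexin relative Cntnap4 rose 1.22-fold, Sez6 1.23-fold, Rasa4 1.27-fold, Sh3bgr 1.52-fold, Gcnt1 1.57-fold and the unnamed gene 6530403H02Rik 1.59-fold. For each of the 24 genes with the smallest p, 12 in each direction, no cKO library overlapped a WT library. Their choice by p from these same libraries favours such a separation.

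Markers of granule cells moved in both directions. Of 24 tested markers, 4 rose (Calb2, Etv1, Kcnk9, Gabrd) and 6 fell (Gabra6, Reln, Neurod2, Grm4, Zic1, Pax6), against 5 and 10 when adjusted over the list alone. Reln, the secreted glycoprotein reelin, fell by 15.5%, and Etv1, a transcription factor of maturing granule cells, rose 1.15-fold (edgeR adjusted p = 4.88e-05 and 0.00033). As a set the list did not pass (camera adjusted p = 0.233), though without cKO replicate 4 its adjusted p was 0.0221. Among 10 tested markers of unipolar brush cells and cerebellar nuclear neurons, 2 fell, among them Eomes, and Calb2 rose (3 fell and 1 rose when adjusted over the list alone), and the set did not pass (camera adjusted p = 0.418).

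Markers of cerebellar inhibitory interneurons were lower as a set. Of 15 tested members 13 had a lower level in cKO, with a median log2 fold change of −0.08 (camera adjusted p = 7.66e-05; adjusted p = 0.0844 with an estimated correlation). A single member, Lgi2, passed the test across all genes, and 7 were lower when adjusted over the list alone. Lgi2, a secreted leucine-rich protein, fell by 13.4% (log2 fold change −0.21, SE 0.04). It lost its call with surrogate variables (−0.20, SE 0.05, adjusted p = 0.114) and, in fits added after the data were seen, with a tissue score described below as a covariate (−0.18, SE 0.05, adjusted p = 0.104) or without the 4 libraries highest in that score (−0.19, SE 0.05, adjusted p = 0.149), as its SE widened more than its fold shrank. Ptprk, Slc6a5 and Prkcd had log2 fold changes of −0.11, −0.15 and −0.13 without passing (edgeR adjusted p = 0.0901, 0.105 and 0.150).

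Genes of GABA receptors and inhibitory synapses were also lower as a set, though 6 of the 18 tested members had positive log2 fold changes. Of the 18, 4 fell, among them Gabra6 and Gabrb2, and Gabrd, the δ subunit of extrasynaptic receptors, rose 1.11-fold, against 5 lower and 1 higher when adjusted over the list alone. Gabrd (log2 fold change 0.15, SE 0.03, edgeR adjusted p = 0.0153) lost its call with surrogate variables (0.17, SE 0.04, adjusted p = 0.0905) and without the 4 libraries with the highest tissue score (0.18, SE 0.04, adjusted p = 0.0584). The set's camera adjusted p was 0.000457 (adjusted p = 0.0743 with an estimated correlation). Without the 4 genes that fell, an alternative added after the data were seen and one that raises the p of any such set, the adjusted p was 0.721. Gabrb2, the β2 subunit, fell by 13.9% (edgeR adjusted p = 0.00042), from 475 ± 19.4 to 409 ± 17.7 CPM (SD, n = 6 each).

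Some of the genes that lie next to Gabra6 fell with it. In a list of 9 tested neighbours, 4 fell, among them Gabrb2 and Pttg1, and 5 were not called, 7 had a negative and 2 a positive log2 fold change, the median log2 fold change was −0.12, and 6 were lower and 1 higher when adjusted over the list alone (camera adjusted p = 2.78e-06; adjusted p = 0.0743 with an estimated correlation). Pttg1, which encodes the anaphase inhibitor securin, lies 1.11 Mb from Gabra6 and fell by 56.8%, from 18.8 ± 3.10 to 8.25 ± 3.54 CPM (SD, n = 6 each). Within 10 Mb of Gabra6, 11 of 101 other tested genes were called, 9 of them lower, against 382 of 14775 elsewhere (two-sided Fisher's exact test, odds ratio 4.60, 95% interval 2.20 to 8.73, p = 7.18e-05). The odds ratio was 8.87 within 5 Mb (5 of 26 called, Fisher's exact p = 0.000522) and 2.04 within 20 Mb (14 of 271, Fisher's exact p = 0.0188). Ublcp1, a phosphatase gene 2.15 Mb away, fell by 21.5%. With a fold minimum of 1.2 no window gene was among the 27 calls and p was 1.0. Around Crhr1, on the same chromosome, 10 of 294 tested genes within 10 Mb were called, close to the share elsewhere (383 of 14582, Fisher's exact p = 0.360). In the list of 18 tested genes near Crhr1 Mapt, which encodes tau, rose by 10.1% (2 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.679). Mapt (log2 fold change 0.14, SE 0.03, adjusted p = 0.00544) lost its call with surrogate variables (0.13, SE 0.04, adjusted p = 0.122).

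**Figure D2:**
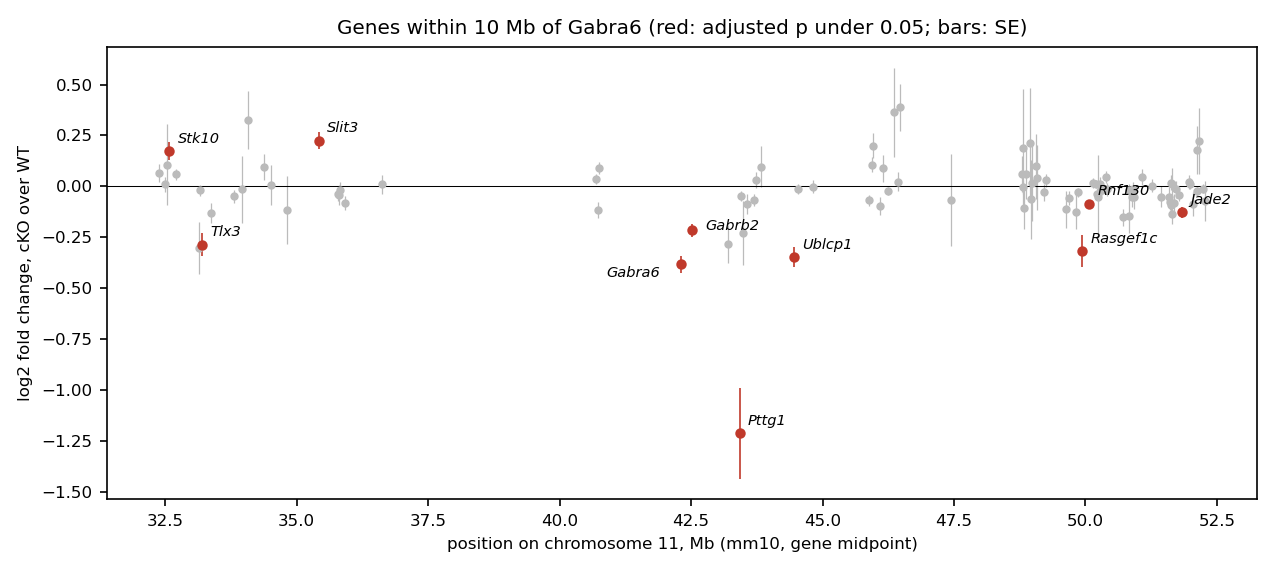
Log2 fold change (cKO over WT, bars are SE) of the tested genes reported here within 10 Mb of Gabra6 against the gene's midpoint on chromosome 11 in Mb (mm10), with called genes in red. Gabra6, Gabrb2, Pttg1 and Ublcp1 lay below 0, while Slit3 and Stk10 lay above it.

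Presynaptic release genes split evenly. Of 21 tested, Syt1, Cplx2 and Syn2 fell and Syt2, Unc13a and Bsn rose (4 and 4 when adjusted over the list alone, camera adjusted p = 0.364). Cplx2, a complexin that binds the vesicle fusion complex, fell by 17.4%, whereas Syt2, a second fast calcium sensor, rose 1.16-fold (edgeR adjusted p = 4.35e-05 and 3.80e-05). Of 26 ion channel and excitability genes, Kcnc1, Kcnk9 and Kcnj3 rose and Kcna2 fell (4 and 1 when adjusted over the list alone, camera adjusted p = 0.246). Kcna2, a delayed rectifier subunit of axons and terminals, fell by 17.6% (edgeR adjusted p = 5.10e-05) and Kcnk9, a leak channel of granule cells, rose 1.28-fold. Kcnj3 kept its call in only 2 of the 12 fits that left out a library, those without cKO replicate 5 or WT replicate 5, and its adjusted p in the other 10 was 0.0526 to 0.110. Of 19 genes of cerebellar plasticity signalling, Nos1 and Camk2b rose and Cnr1, the cannabinoid receptor of parallel fibre terminals, fell by 11.8% (5 and 1 when adjusted over the list alone, camera adjusted p = 0.364). Camk2b lost its call without WT replicate 1, 2, 4 or 6 or cKO replicate 3, 4 or 5 (adjusted p = 0.0570 to 0.0864). Of 25 glutamate receptor genes 2 fell, among them Grm4 (3 lower when adjusted over the list alone, camera adjusted p = 0.233). Grm4 (log2 fold change −0.19, SE 0.04, adjusted p = 0.0171) had an adjusted p of 0.0518 without WT replicate 3. It also lost its call with surrogate variables (−0.16, SE 0.06, adjusted p = 0.326), with the tissue score (−0.16, SE 0.05, adjusted p = 0.195) and without the 4 libraries highest in it (−0.13, SE 0.05, adjusted p = 0.401). In those 3 fits Kcnj3 and Camk2b lost their calls too (adjusted p = 0.292 to 0.548 and 0.0693 to 0.382), with log2 fold changes of 0.092 to 0.095 for Kcnj3 (0.108 before) and 0.110 to 0.145 for Camk2b (0.112 before), as their SE widened from 0.03 to between 0.03 and 0.04.

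**Figure D3:**
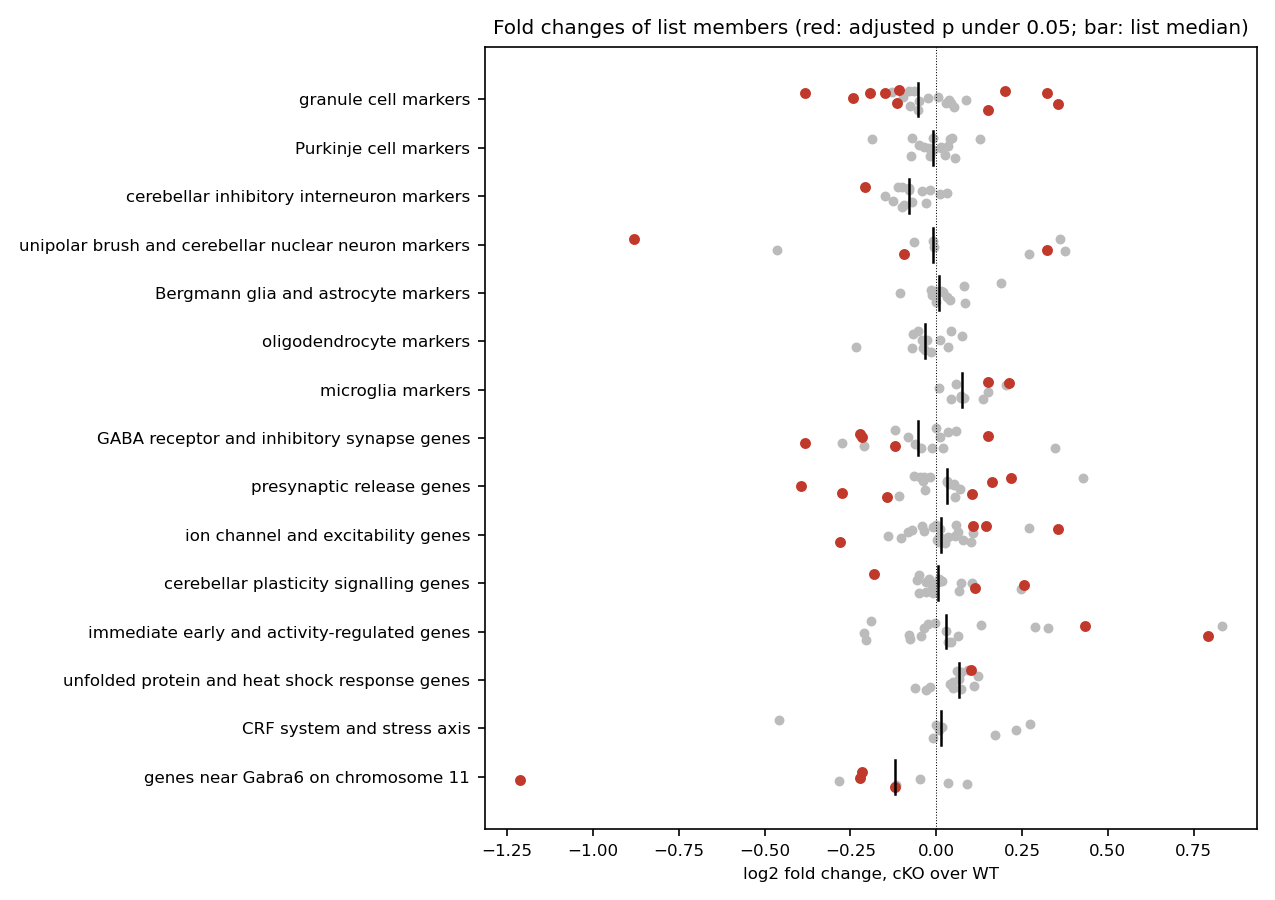
Log2 fold change (cKO over WT) of each tested member of 15 gene lists, with called genes in red and the list median as a bar. Interneuron markers and the neighbours of Gabra6 had medians of −0.08 and −0.12, and the granule cell list held 10 called genes on both sides of 0.

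Activity-regulated genes changed in 2 cases. Of 19 tested, Arc and Npas4, a neuronal transcription factor induced by depolarisation, rose (3 higher when adjusted over the list alone), and Npas4 went from 3.96 ± 0.86 to 6.96 ± 1.14 CPM (SD, n = 6 each, log2 fold change 0.79, SE 0.13, edgeR adjusted p = 0.00137). With surrogate variables Npas4 lost its call, at a smaller log2 fold change with a wider SE (0.63, SE 0.15, adjusted p = 0.0698). The set did not pass (camera adjusted p = 0.0920). Growth factor genes Ntrk3 fell by 15.1% and its ligand Ntf3 fell by 42.8%, the members called among 14 (2 lower and 1 higher when adjusted over the list alone, camera adjusted p = 0.0562). Among 15 genes of granule cell development, the cell cycle gene Ccnd1 fell by 18.05% and Ptch1, the Sonic hedgehog receptor, rose 1.07-fold (2 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.233). Ptch1 kept its call only without cKO replicate 2, cKO replicate 6 or WT replicate 6 and had an adjusted p of 0.0504 to 0.0786 in the other 9 fits, and it lost its call with surrogate variables, with the tissue score and without the 4 libraries highest in it (log2 fold change 0.108 to 0.130 against 0.104 before, SE 0.03 to 0.04 against 0.03, adjusted p = 0.0928 to 0.261) and with thinned counts (adjusted p = 0.112). Per2 rose 1.22-fold among 16 clock genes (2 higher when adjusted over the list alone, camera adjusted p = 0.365). Per2 (log2 fold change 0.28, SE 0.05, adjusted p = 0.00384) lost its call with surrogate variables (0.24, SE 0.07, adjusted p = 0.166) and without the 4 libraries with the highest tissue score (0.24, SE 0.06, adjusted p = 0.0928). Adcy1, a calcium-stimulated adenylyl cyclase, rose 1.09-fold among 27 genes of cAMP signalling (1 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.804). Adcy1 (log2 fold change 0.13, SE 0.03, adjusted p = 0.00975) lost its call with surrogate variables (0.13, SE 0.04, adjusted p = 0.189).

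Markers of microglia and genes of the unfolded protein and heat shock response were higher as sets under the preset correlation. All 12 microglia markers had a higher level in cKO, 2 of them called (Cx3cr1 and Csf1r, also 2 when adjusted over the list alone), with a median log2 fold change of 0.08 (camera adjusted p = 0.00243; adjusted p = 0.599 with an estimated correlation). Cx3cr1, the fractalkine receptor, rose 1.16-fold and Csf1r 1.11-fold. Cx3cr1 lost its call without WT replicate 1, 2, 3, 5 or 6 or cKO replicate 3 (adjusted p = 0.0548 to 0.0929), and Csf1r without WT replicate 1, 3, 4 or 5 or cKO replicate 1, 2 or 3 (adjusted p = 0.0574 to 0.108). Both lost their calls with surrogate variables, with the tissue score and without the 4 libraries highest in it (adjusted p = 0.243 to 0.630 for Cx3cr1 and 0.370 to 0.698 for Csf1r). Here the log2 fold changes shrank, from 0.21 (SE 0.05) to 0.19 (SE 0.07) with the score, 0.14 (SE 0.07) with surrogate variables and 0.14 (SE 0.06) without the 4 libraries for Cx3cr1, and from 0.15 (SE 0.04) to 0.11 (SE 0.04), 0.098 (SE 0.05) and 0.087 (SE 0.04) for Csf1r. Csf1r lost its call also with thinned counts (adjusted p = 0.0905). Among 16 genes of the unfolded protein and heat shock response, the chaperone gene Hspa8 rose 1.07-fold, and 3 were higher when adjusted over the list alone (camera adjusted p = 0.0038; adjusted p = 0.599 with an estimated correlation). Hspa8 (log2 fold change 0.10, SE 0.02, adjusted p = 0.00815) lost its call with surrogate variables (0.10, SE 0.03, adjusted p = 0.233) and without the 4 libraries with the highest tissue score (0.10, SE 0.03, adjusted p = 0.166), as its SE widened. Herpud1 and Atf4 had log2 fold changes of 0.09 and 0.11 (edgeR adjusted p = 0.0764 and 0.108).

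No marker of Purkinje cells, Bergmann glia and astrocytes, oligodendrocytes or their precursors, endothelial and mural cells, choroid plexus and ependyma, meninges and fibroblasts, erythrocytes, or brainstem and midbrain passed edgeR's test. Of these 95 tested genes 7 had an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 1. The Purkinje gene Car8, a regulator of calcium release, came closest with a log2 fold change of −0.19 (edgeR adjusted p = 0.0762) and was the 1 lower when the 18 Purkinje genes were adjusted over the list alone. A further 8 lists held no called gene under edgeR: the CRF system and stress axis, glucocorticoid-responsive, parallel fibre synapse organiser, nuclear oxidative phosphorylation, ribosomal protein, interferon and antigen presentation, perineuronal net and matrix, and sex-linked genes. Of their 123 genes 14 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 1, and adjusted over the list alone the interferon list held 1 higher gene and the other lists held 0. None of these lists passed as a set (the lowest camera adjusted p was 0.0562, for ribosomal protein genes). In the CRF list, Crhr2 measured 0.67 ± 0.38 CPM in cKO (SD, n = 6, log2 fold change 0.23, edgeR adjusted p = 0.811).

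Principal component 1 of the 12 libraries carried 20.6% of the variance and differed between the genotypes (two-sided exact permutation test, p = 0.00649). The genotypes overlapped on it, as WT replicate 5 (3.46) lay above cKO replicate 4 (0.979) and cKO replicate 6 (1.33). Ddn and Nrgn, neuronal genes abundant in forebrain, were among 21 forebrain and midbrain genes chosen after the data were seen. A tissue score was formed from these 21 genes. It averaged −0.48 ± 0.71 in WT and 0.48 ± 0.71 in cKO (SD, n = 6 each), a difference that the choice of genes favours and that is not a test of the genotypes. WT replicate 1 and cKO replicate 1 lay at opposite ends of both component 1 (−17.9 and 16.2) and the score (−1.23 and 1.43). The difference in component 1 can therefore not be told apart from one in the score. The brainstem and midbrain list fixed in advance, with 4 tested genes, had a camera adjusted p of 0.418. With that score as a covariate the called genes numbered 96 higher and 87 lower, and without the 4 libraries with the highest score 89 higher and 68 lower. Both alternatives were added after the data were seen. With 3 surrogate variables 55 were higher and 57 lower, and without WT replicate 3 the genes lower in cKO numbered 138. All 24 genes with the smallest p kept their calls in each of these fits.

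The authors' deposited table called 563 genes at an adjusted p under 0.05, 274 with a positive and 289 with a negative fold change. Of the 409 genes called here, 400 were among them, all with the same sign. In the authors' deposited table the log2 fold change was 0.02 for Crhr1 and −0.32 for Gabra6. Its folds were smaller than those of edgeR, with a median ratio of 0.860 over the called genes.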

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

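Some values lay far from the rest of their group. The gap of the highest or lowest of 6 libraries to its nearest neighbour exceeded the 95% critical value of Dixon's ratio in 10 of 290 groups examined, where chance would give about 14.5. The tests of counting error and spread, of undeleted transcript and of Crhr1 without WT replicate 5 were chosen only after the result was seen. So were those of labels with the tissue score and of granule cell number. The window count around Gabra6 was planned, but its reading for DNA at the driver locus was written after the result was seen.

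In WT replicate 5, Arc measured 27.1 CPM against at most 24.4 in the other WT libraries, and Itpr3 58.5 against at most 52.5. In WT replicate 2 the interferon genes Irf9 and Bst2 were highest at 26.0 and 4.26, with nearest values of 22.4 and 2.96. In cKO replicate 2, the interferon gene Ifit3 was highest at 31.6, next 17.0, and the microglial gene Cx3cr1 at 17.9, next 15.5. In cKO replicate 6, the choroid plexus genes Cldn2 and Aqp1 were 6.49 and 5.61, next 2.62 and 2.31, the fibroblast gene Lum was 6.61, next 4.58, and Ltbp2 was lowest at 123, next 137.

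The numbers of called genes exceeded those of other groupings. Of 100 drawn splits of the 12 libraries into 6 and 6, the real one included, only the real split (1 of 100) gave 409 genes in all, 196 in one direction or 213 in the other, and the highest of the other splits were 85 in all and 72 in one direction. The real split likewise gave the smallest camera p in 1 of 100 for GABA receptor genes (4.15e-05, next 0.00116) and for the neighbours of Gabra6 (8.42e-08, next 4.56e-06), and 3 of 100 splits gave as small a p for interneuron markers (4.64e-06, lowest other 2.84e-06). For those 3 lists fewer than 5 of 100 splits did as well, the mark set in advance against a chance division of the libraries. The splits were run only for the 5 lists that had passed among 33, which favours small shares. They therefore do not decide the matter for interneuron markers, where other splits reached as small a p. Those splits (2.84e-06 and 2.99e-06) each kept 5 of the 6 WT libraries together and so were close to the real one. The latter also gave the 85 called genes. For GABA receptor genes and the neighbours of Gabra6 only the real split reached as small a p. This argues against a chance division of the libraries, though the selection of lists weakens the argument. With an estimated correlation none of the 3 lists passed (adjusted p = 0.0743, 0.0743 and 0.0844), and 100 splits cannot give a share under 1 of 100. For microglia markers 14 of 100 splits gave as small a p (0.00029, lowest other 6.81e-07), and for the unfolded protein and heat shock list 11 of 100 (0.00058, lowest other 4.38e-09), so chance is not excluded for these.

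Crhr1 did not differ between the genotypes although the cKO libraries are labelled as its knockout. Too few counts or too wide a spread is argued against by the 95% interval of the log2 fold change, whose lower bound of −0.0613 leaves no room for a fall by a sixth. A wrong label was examined with genes called without the library in question, and 1 of the 12 libraries, WT replicate 5, lay nearer the other genotype, as a wrong label predicts. Its position was 0.159, between the other WT libraries (−1.21 to −0.646) and the cKO libraries (0.368 to 1.19), where −1 and 1 are the group means. With the tissue score, in which it was the highest WT library (0.756), as a covariate its position was −0.312 and no library was misplaced. Its Gabra6 level, 710 CPM, lay above the highest cKO value of 669. Its Chrnb4 level, 3.84 CPM, lay above the highest cKO value of 1.23. Chrnb4 was named for its small p with WT replicate 5 counted as WT, so its level does not bear on the label. A wrong label on 1 library is argued against by turning each of the 12 labels in turn, since 0 of them gave as many as the 409 called genes (22 to 267) and the Crhr1 adjusted p was at least 0.495. That WT replicate 5 alone hides a fall is argued against by the fit without it, where the log2 fold change of Crhr1 was 0.00647 (95% interval −0.0765 to 0.0895). Against wrong labels on more libraries stand the 11 libraries on their own side, the separation of all 6 cKO from all 6 WT libraries in Gabra6 and the at most 85 genes called in the 99 other splits drawn, but not all splits were run and these values do not decide it. Crhr1 ran from 88.7 to 105 CPM over the 12 libraries (highest over lowest 1.18), which limits the fall that other labels could bring out but leaves room for a small one. Reads from undeleted parts of the gene, or from cells without Cre, may keep the total level (log2 fold change 0.0182), but without counts per exon this cannot be told apart from an intact gene.

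Some genes near Gabra6 fell with it, 9 of the 101 tested within 10 Mb, while 2 rose and the others were not called. Fewer granule cells as the sole source of the fall of Gabra6 are argued against by the 23 other granule cell markers. Their median log2 fold change was −0.0501 (SD 0.151) against −0.38 for Gabra6. A smaller loss of granule cells stays open. Of the 24 markers, Gabra6 included, 10 were lower and 5 higher when adjusted over the list alone. Clustering of called genes by chance is argued against by the windows of 10 Mb around tested genes more than 20 Mb from Gabra6 that held at least 50 tested genes, of which 0% (0 of 13783 overlapping windows) had a share of called genes as high as the 10.9% around Gabra6, the highest being 10.1% on chromosome 5. A candidate explanation is DNA around the driver locus that differs from the WT mice, either the driver's insertion or a flanking stretch from another strain. It was examined only by the planned window count (Fisher's exact p = 7.18e-05). What that count would show for this explanation was written after its result was seen, so it is no separate test. An effect of the loss of the receptor on these genes stays open, since such DNA, if present, would come with the genotype, and neither it nor the loss of the receptor could be seen in gene totals.

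Forebrain and midbrain genes were higher in some cKO libraries, with the score highest in cKO replicate 1 (1.43), cKO replicate 3 (0.96), cKO replicate 2 (0.76) and WT replicate 5 (0.76). All 21 genes of the score, chosen after seeing the data, had positive log2 fold changes (median 0.58), but 2 were called, among them Ddn, and the most abundant, Nrgn and Slc17a6 (the latter also a gene of cerebellar neurons), measured 32.5 ± 12.6 and 35.8 ± 9.86 CPM in cKO (SD, n = 6 each). Tissue from next to the cerebellum as the source of the 24 genes with the smallest p is argued against, since all 24 stayed past the threshold with the score as a covariate. So did Arc (log2 fold change 0.36, from 0.43) and Npas4 (0.68, from 0.79). AI506816 also stayed past it, but its log2 fold change shrank from 3.20 to 2.02. How much such tissue adds to the rise of AI506816 therefore stays open. Genes with the smallest p are the most likely to stay, so the argument from the 24 genes does not extend to the other calls. The score holds forebrain and midbrain genes only, so other neighbouring tissue was not covered. With the score 183 genes were called, 166 of them among the 409. The 243 that lost their calls had a median of 0.91 of their former log2 fold change (quartiles 0.844 and 1.013), 1 of them less than 0.5, while their SE widened by a median of 1.25 times, so their lost calls do not by themselves point to such tissue. It stays open how much it adds to those whose fold shrank, such as Cx3cr1 and Csf1r, and a real rise of such genes in the cerebellum was not tested.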

How the results depend on the processing

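All 24 genes with the smallest p kept direction and call in every fit except the one against a fold minimum of 1.2, where 16 did. Crhr1 passed in none of its 24 alternatives (log2 fold change 0.00 to 0.07). Gabra6 kept its call in 23 of 24 and with the fold minimum had an adjusted p of 0.362 at the same log2 fold change, −0.38, since that test asks for more than 1.2-fold. Of all 55 named genes that passed, 55 did so under other scalings, filters, DESeq2 and limma-voom, 53 with thinned counts, 46 with the tissue score as covariate, 43 without the 4 libraries with the highest score, 40 with surrogate variables and 18 with the fold minimum. No paired analysis was possible because the labels give no pairing between animals. The planned sex covariate was not run. The cause of the changes below was not tested. Tests with the score and without the 4 libraries or chosen members were chosen after seeing the data.

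Genes higher and lower in cKO numbered 196 and 213, and 55 and 57 with surrogate variables, 8 and 19 with the fold minimum, 96 and 87 with the score, and 89 and 68 without the 4 libraries with the highest score. DESeq2 gave 282 and 295. Without a library, those higher ran from 134 to 214 and those lower from 138 (without WT replicate 3) to 248. The window around Gabra6 had a Fisher's exact p of 1.0 with the fold minimum, 0.000522 within 5 Mb and 0.0188 within 20 Mb.

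With an estimated correlation the adjusted p of the 5 called lists were 0.0844 (interneurons), 0.599 (microglia), 0.0743 (GABA receptors), 0.599 (unfolded protein response) and 0.0743 (neighbours of Gabra6). With fry they were 0.188 for microglia, 0.159 for the unfolded protein response, 0.0123 for granule cell development and 0.0057 for growth factors. Without its 4 called genes on chromosome 11 the GABA receptor list had 0.721, which removing called members favours, so this does not show that position carries the set. Ribosomal genes had 0.0428 with the filter on CPM and 0.0227 with the score. Growth factors and the markers of unipolar brush and cerebellar nuclear neurons also had 0.0227 with the score. Tbr1 and Slc17a6 belong to both that marker list and the score, so the list's value with the score is not independent of its own members.

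Leaving out 1 library let lists that had not passed reach an adjusted p under 0.05. Granule cell markers ran from 0.0221 (without cKO replicate 4) to 0.426, choroid plexus from 0.00036 (cKO replicate 6) to 0.864, glucocorticoid-responsive genes from 0.0439 (WT replicate 1) to 0.558, oxidative phosphorylation from 0.0417 (cKO replicate 4) to 0.692, and interferon genes from 0.00852 (WT replicate 2) to 0.754. Activity-regulated genes ran from 0.00679 to 0.372 (passing without cKO replicate 2 or WT replicate 3, 4 or 5), ribosomal genes from 0.00886 to 0.222 (WT replicate 1 or 6, cKO replicate 1, 2, 3 or 6), growth factors from 0.0194 to 0.104 (WT replicate 1 or 2, cKO replicate 1 or 3) and sex-linked genes from 0.0233 to 0.297 (cKO replicate 1 or 6). The 5 called lists kept their calls in all 12 fits. At this depth, simulated folds of 1.1 were recovered in 31.2% of changed genes, all with a mean of at least 1 CPM. Smaller changes were therefore mostly not detectable.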

Other observations

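Other genes with large changes were mostly rare transcripts, picked here after their values were seen. Of the 8 genes above 2-fold, AI506816, a gene of unknown function, rose 9.19-fold, from 0.54 ± 0.48 to 5.10 ± 3.30 CPM (SD, n = 6 each, edgeR adjusted p = 0.00042). WT replicate 5 measured 1.48 CPM against 0.126 to 0.461 in the other WT libraries, and without it the WT mean was 0.355 CPM and the rise 13.4-fold (7.36 to 10.3-fold without any other library). Its values in cKO replicates 1, 2 and 3, the cKO libraries with the highest tissue score, were 10.6, 5.92 and 6.595 CPM against 2.07 to 3.25 in the other 3, and with that score as a covariate its log2 fold change went from 3.20 (SE 0.47) to 2.02 (SE 0.18). Xaf1, an interferon-inducible regulator of apoptosis on chromosome 11, rose 2.26-fold, from 4.96 ± 1.84 to 11.7 ± 4.53. In cKO replicate 2 it measured 20.8 CPM against at most 10.8 in the other cKO libraries. Without that library the rise was 1.92-fold (edgeR adjusted p = 0.00334), and without any other library it was 2.12 to 2.77-fold. WT replicate 6 (8.571 CPM) lay just below the lowest cKO library (8.578 CPM). Ddn, which encodes the dendritic protein dendrin, rose 3.19-fold (edgeR adjusted p = 0.0260), and lost its call without WT replicate 1, 2, 3, 4 or 6 (adjusted p = 0.0515 to 0.0815). Slc26a5, the motor protein prestin, had a log2 fold change of −1.23 at levels below 1 CPM (edgeR adjusted p = 0.0331) and kept its call only without cKO replicate 4, cKO replicate 5 or WT replicate 5 (adjusted p = 0.0537 to 0.101 in the other 9 fits). Chrnb4 and Chrna3 lie beside each other on chromosome 9 and fell together.

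Pttg1 and Ublcp1, 2 neighbours of Gabra6 picked after their values were seen, were compared between animals of one genotype, and neither correlation passed after adjustment. Their log2 levels had a Pearson r of 0.858 within WT (exact permutation p = 0.0306, Benjamini-Hochberg 0.0611 over the 2 genotypes) and 0.811 within cKO (exact permutation p = 0.0694, adjusted 0.0694), n = 6 each. Spearman's rho was 0.886 (exact permutation p = 0.0333) and 0.714 (p = 0.136). Without the 2 libraries farthest from the median of Pttg1, r was 0.974 in WT and 0.083 in cKO, so in cKO the relation rests on those libraries. They were cKO replicates 4 and 6, with Pttg1 at 3.795 and 3.61 against 10.1 to 11.1 CPM in the other 4. Of 10000 random pairs of genes, 0.17% had as high an r in both genotypes.

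Families of genes sharing a symbol root were tested for an excess of called members, and of 245 families none passed (one-sided Fisher's exact test on edgeR calls) and 10 had an unadjusted p under 0.05. The lowest p belonged to the synaptotagmins, with Syt2 higher and Syt1, Syt4 and Syt9 lower among 16 tested (adjusted p = 0.167).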
